A study of Mus musculus with 8 samples.

How the data were processed

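Small RNA was sequenced from the prefrontal cortex of C57BL/6 mice at 12 weeks of age, in 4 wild-type libraries and 4 libraries from Fkbp5 knockout mice. Per the labels' protocols, RNA was isolated with silica columns that keep and then enrich short RNA, libraries were made with a NEXTflex small RNA kit, products were selected by size on a gel, and paired reads of 100 bases were taken on an Illumina sequencer. Per the submitters' processing notes, the tools named were cutadapt 1.11, Bowtie 1.1.2, HTSeq 0.6.1p1 and edgeR, and the genome build was mm10. The notes give no order or settings for these tools.

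Each deposited file lists 1915 mature miRNA names with 1 value each. Per the file headers the authors call these values normalized counts, so they were handled as a score, a number of no fixed unit, and not as raw counts. The values pointed elsewhere than the headers. All were whole numbers, library totals ran from 16.2 to 21.6 in units of 1000000, and each whole number from 1 to 20 occurred in every library, so no scaling between libraries was visible. The header was followed. The planned main test, edgeR's quasi-likelihood test, needs raw counts and was therefore not run, and neither were the other planned count models or the thinning of libraries to 1 total. limma took their place after the unit had been found, and 1 exploratory limma fit with other settings had been looked at by then.

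The values were rescaled between libraries by a trimmed mean of log ratios, with 30% of the ratios and 5% of the levels trimmed at each end. The factors ran from 0.838 to 1.21. A miRNA was tested if it reached a value of 10, scaled to the median library, in at least 4 libraries and a total of 15, which left 599 miRNAs holding 99.99% of all values. Rescaled values were moved to log2(value + 1) and compared by genotype with limma 3.58.1 in R 4.3.3, using empirical Bayes moderation with a mean-variance trend and Benjamini-Hochberg adjustment at 0.05. All fold changes are on that log2 scale, which understates the change of low miRNAs. Group values are means of rescaled values ± SD. Counts of higher and lower miRNAs go by the sign of the log2 fold change, the difference of mean log2 values, which for some differs from that of the mean rescaled values. Nothing in the labels says whether the libraries are separate animals, so p-values measure the spread between these samples.

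Before the data were examined, 18 lists of miRNAs were fixed, for cell types, families and imprinted clusters, along with the rule for naming miRNAs. That rule takes the miRNAs past the threshold, filled up to 20 with the smallest unadjusted p, then the 5 most abundant, and up to 4 abundant members of each list. The 17 lists with at least 3 tested members were compared with the other miRNAs by limma's camera at a preset correlation of 0.01. camera with an estimated correlation and fry were run beside it. For 141 hairpins with both arms at a mean of at least 20, the log2 ratio of the 5p to the 3p arm, with 0.5 added to each, was tested with limma. Library measures were compared by two-sided exact permutation tests over 70 arrangements, whose smallest possible p is 0.0286. Of the mature names, 1849 were matched to hairpin genes of the GRCm38 annotation, which is the assembly mm10 names, and positions are given on it.

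The procedure was tested on simulated data drawn from the levels and spread of these libraries. With 200 of 599 miRNAs changed, limma recovered 62.7% of those changed 1.5-fold, 83.6% at 2-fold and 97.6% at 4-fold, and 3.73% of its calls were false. With only 12 changed, it recovered 7.5%, 60.8% and 92.5%. The list test recovered the Dlk1-Dio3 list, raised 2-fold, in 100% of simulations, a change far above most list medians seen here. The arm test recovered 81.5% of the hairpins changed 2-fold among 140. Each miRNA was drawn independently, so the simulations leave out correlation between list members, estimated at 0.86 for the miR-200 family. They cannot show how often lists of correlated members are called falsely. Other scalings, filters, pseudocounts, list tests, a block on the replicate numbers and the omission of each library were tried as alternatives.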

Results

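MicroRNA levels were measured by small RNA sequencing in the prefrontal cortex of 12-week-old mice, in 4 wild-type libraries (replicates 1, 2, 3 and 4) and 4 Fkbp5 knockout libraries (replicates 1, 2, 4 and 5). Fkbp5 encodes a co-chaperone of Hsp90 that lowers the affinity of the glucocorticoid receptor for its hormone, and lies on chromosome 17 at 28398753 to 28486149 (GRCm38). Its messenger RNA is not read by this assay, so the data do not check the genotype labels. In units of 1000000, library totals were 19.1 ± 2.82 in wild type and 18.6 ± 0.929 in the knockout (SD, n = 4 each; two-sided exact permutation p = 0.771). The libraries held 1008 ± 17.5 and 1006.75 ± 30.9 miRNAs with a value above 0 (exact p = 0.943), and 585 of the 1915 names were at 0 in every library.

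The comparison asks which cortical miRNAs differ when Fkbp5 is missing. The miRNAs that dominate this tissue were at nearly equal levels in both genotypes. miR-128-3p, a miRNA enriched in neurons, averaged 4515270 ± 723385 in wild type and 4443440 ± 660388 in the knockout (SD, n = 4 each), a log2 fold change of -0.02 ± 0.14 (SE). The next 4 by abundance were miR-9-5p (-0.04), let-7c-5p (-0.01), miR-26a-5p (-0.02) and let-7a-5p (0.01). The largest log2 fold change among the miRNAs named by the rule was that of miR-690, at 324.6 ± 137 in wild type and 703 ± 128 in the knockout, and it did not pass correction. It was 1.20 ± 0.27, close to that of miR-200b-3p (-1.18 ± 0.67), which varied far more between libraries. Outside the rule, miR-429-3p was at -1.32 ± 0.82 (not past correction).

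By limma with Benjamini-Hochberg adjustment, 0 of 599 miRNAs passed 0.05, and 25 had an unadjusted p under 0.05 (8 higher and 17 lower in the knockout) where chance gives 29.95. With upper quartile scaling the 25 became 20, with 12 higher and 8 lower, and the values as deposited gave 4 higher and 5 lower. The median absolute log2 fold change was 0.11, 95.5% of the miRNAs differed by less than 1.5-fold, and the 95% interval excluded a 2-fold change for 86.8%. The groups did not overlap for 12 miRNAs (2.0%, against 2.86% by chance). Correlations of log2 values ran from 0.984 to 0.994 within genotypes and from 0.987 to 0.994 between them, across miRNAs, which are not independent replicates.

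**Figure D1:**
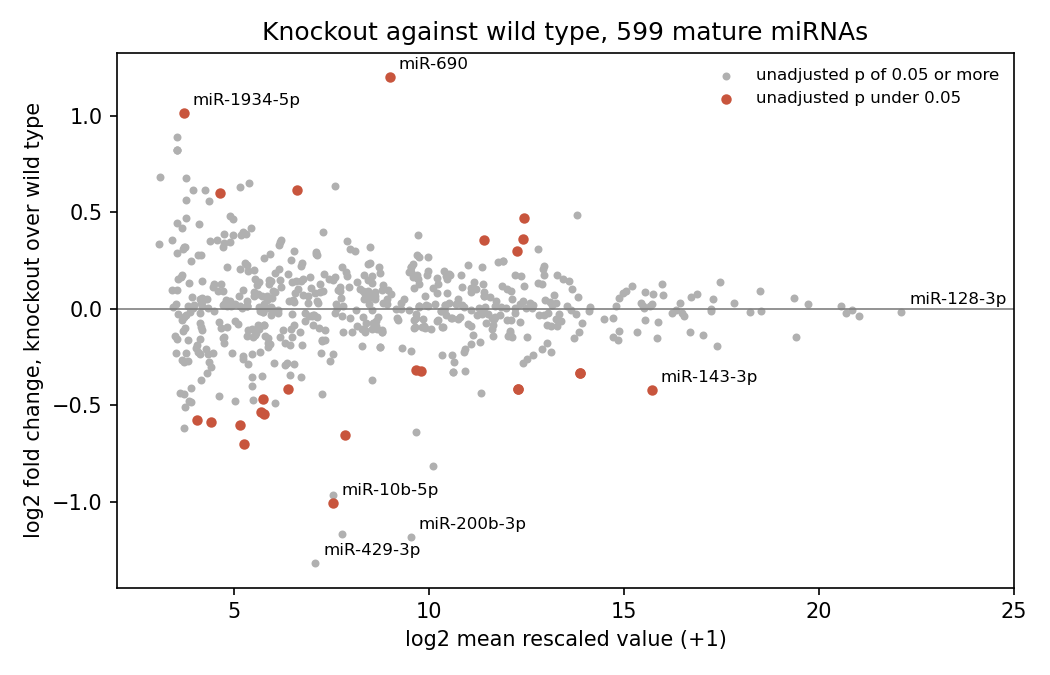
Log2 fold change of each tested miRNA (vertical axis, knockout over wild type) against its log2 mean rescaled value (horizontal axis). Red points are the 25 miRNAs with an unadjusted p under 0.05, and the most abundant, miR-128-3p, lies at -0.02.

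None of the 20 miRNAs with the smallest p passed the threshold. The first was miR-690, whose hairpin lies in an intron of Fgf12 on chromosome 16 (28599935 to 28600043). It was 2.29-fold higher in the knockout, with a log2 fold change of 1.20 ± 0.27 and an adjusted p of 0.560 by limma, and each of the 4 knockout libraries was above each wild-type library. miR-1934-5p was at 7.65 ± 2.19 in wild type and 16.6 ± 5.11 in the knockout (log2 fold change 1.01 ± 0.32). Of the others with higher mean log2 values in the knockout, miR-433-3p (0.36 ± 0.13), miR-154-5p (0.61 ± 0.25) and miR-1188-5p (0.60 ± 0.24) are encoded on chromosome 12 in the imprinted Dlk1-Dio3 region. miR-3099-3p (0.47 ± 0.15) lies in an intron of Usp29 and miR-346-5p (0.35 ± 0.13) in an intron of Grid1, a glutamate receptor gene. Adjusted p values of the 19 after miR-690 ran from 0.837 to 0.929 by limma.

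The other 13 had lower mean log2 values in the knockout. miR-143-3p, abundant in smooth muscle, averaged 61237 ± 8546 in wild type and 46395 ± 11567 in the knockout (log2 fold change -0.42 ± 0.16). miR-199a-3p and miR-199b-3p, whose values are identical and cannot be told apart here, were at -0.42 ± 0.14. miR-10b-5p, from an intron of Hoxd3 on chromosome 2 (74726070 to 74726137), was at -1.01 ± 0.35, and miR-10a-5p at -0.66 ± 0.24. miR-152-3p, from an intron of Copz2, was at -0.33 and miR-322-3p, on the X chromosome, at -0.32. For miR-143-3p, miR-199a-3p, miR-10b-5p and miR-152-3p, knockout replicate 2 lay within the wild-type range. The rest were miR-224-5p (-0.70), miR-219a-5p (-0.60), miR-542-3p (-0.55), miR-490-3p (-0.54), and miR-101a-3p and miR-101c (both -0.33), whose values nearly coincide.

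**Figure D2:**
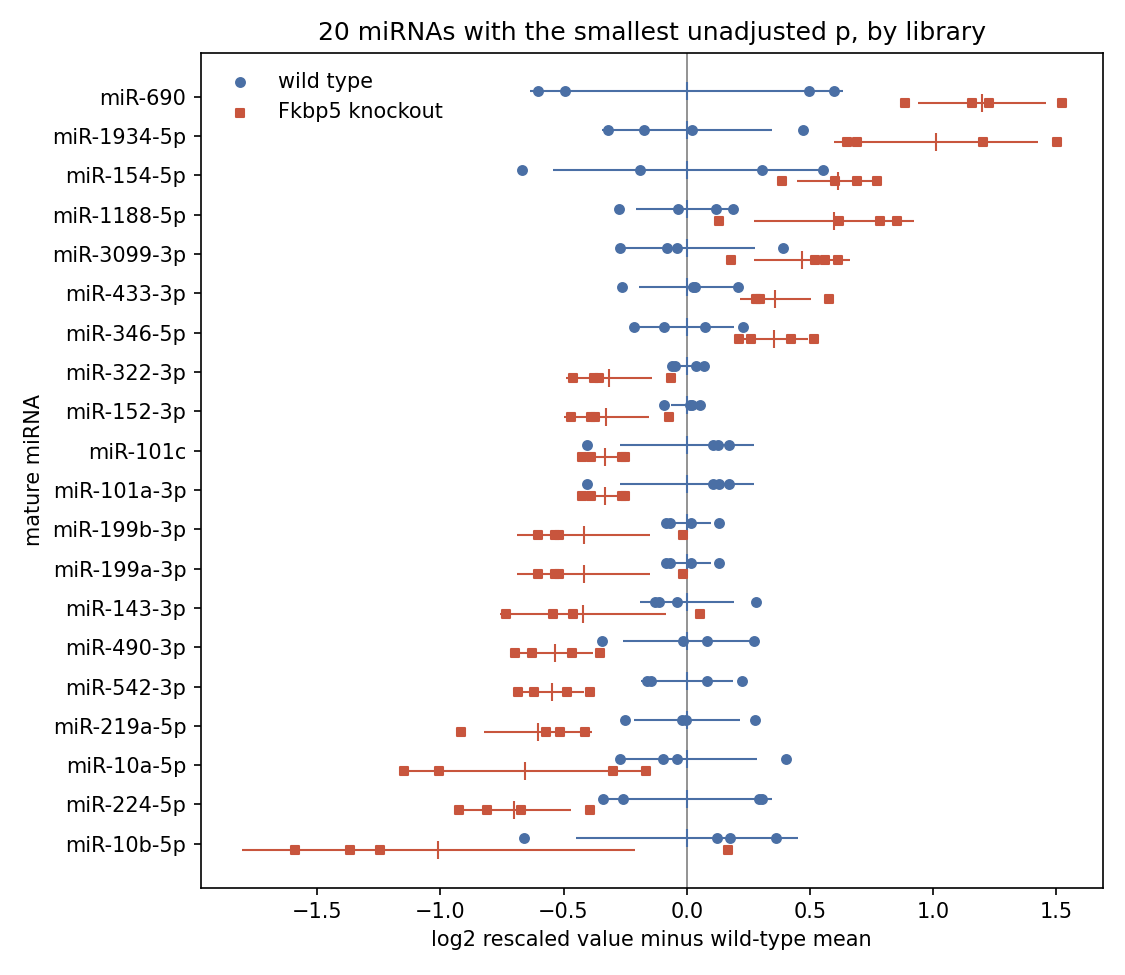
Log2 rescaled value of the 20 miRNAs with the smallest p in each library, minus the wild-type mean (horizontal axis), one miRNA per line; ticks are group means and bars 1 SD over 4 libraries. All 4 knockout libraries lie above wild type for miR-690, while knockout replicate 2 lies near wild type for miR-143-3p and miR-10b-5p.

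Among the lists fixed beforehand, the miR-200 family with the miR-183 cluster, miRNAs of epithelium and of the olfactory bulb, was the 1 that passed camera at the preset correlation. All 7 tested members had lower mean log2 values in the knockout, with a median log2 fold change of -0.96 and a camera adjusted p of 0.00693, and no member passed on its own; the mean rescaled value of miR-96-5p was nearly equal (24.3 and 24.6). The call did not hold when the members' correlation between libraries was estimated: adjusted p = 0.658 with an estimated correlation and 0.843 by fry, and the exact permutation p of the list mean was 0.257. miR-200b-3p averaged 1021 ± 906 in wild type and 451 ± 457 in the knockout, and miR-183-5p 1300 ± 477 and 903 ± 844. Wild-type replicates 2 and 3 and knockout replicate 5 held the high values, and without wild-type replicate 2 or 3 the camera adjusted p was 0.167 or 0.485, and 0.0863 without knockout replicate 2. With 1 library left out the median ran from -0.64 without wild-type replicate 2 to -1.62 without knockout replicate 5.

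Markers of other cells and regions gave no camera call. Of the posterior Hox-cluster list, typical of hindbrain and spinal cord, only miR-10a-5p and miR-10b-5p were tested. Both passed when adjusted over the list alone (smallest value 0.018) and 0 passed over all miRNAs. The exact permutation p of that list's mean was 0.0571. Among 6 endothelial and smooth muscle miRNAs 5 had lower mean log2 values (median -0.10, adjusted p = 0.102), with miR-126a-3p of endothelium at -0.07 ± 0.11 and miR-145a-5p at -0.08 ± 0.22. That adjusted p was 0.658 with an estimated correlation. It was 0.00415 without wild-type replicate 1 and 0.0159 without knockout replicate 2, but 0.539 without wild-type replicate 3 and 0.549 without wild-type replicate 2, where the median turned to 0.0023. Of 7 oligodendrocyte miRNAs 5 had lower mean log2 values (median -0.09, adjusted p = 0.102), among them miR-338-3p (-0.22 ± 0.13), and the adjusted p was 0.658 with an estimated correlation and ran from 0.0381 without knockout replicate 1 to 0.485 without wild-type replicate 3. Astrocyte (median -0.00343, mean 0.012, 6 tested), microglia and leukocyte (median -0.17, 6 tested), red blood cell (0.04, 7 tested, of which miR-486a-5p and miR-486b-5p share their values), choroid plexus and ependyma (0.04, 6 tested) and striated muscle (-0.12, 4 tested) miRNAs had camera adjusted p values between 0.552 and 0.969. The microglia and leukocyte list was mixed, with 3 higher and 3 lower: miR-142a-5p was at -0.37 ± 0.17 and the more abundant miR-150-5p at 0.17 ± 0.14. So was the red blood cell list, with 4 higher and 3 lower: miR-451a was at -0.11 ± 0.20 and the more abundant miR-486a-5p at 0.25 ± 0.17.

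Neuronal and stress-related miRNAs gave no call. Of 17 neuron-enriched miRNAs 12 had higher mean log2 values (median 0.06, adjusted p = 0.522), with miR-124-3p at 665213 ± 151501 in wild type and 680649 ± 73872 in the knockout. Of 12 activity- and CREB-regulated miRNAs 9 had higher mean log2 values (median 0.07, adjusted p = 0.552), and miR-132-3p, induced by CREB, was at 0.08 ± 0.12. The list tied to stress and glucocorticoid signalling had 6 higher and 4 lower (median 0.03, adjusted p = 0.969), with miR-135a-5p at 0.20 ± 0.15 and miR-218-5p at -0.19 ± 0.13. The let-7 (median 0.01), miR-30 (-0.02) and miR-29 (-0.07) families and the miR-17-92 clusters (median -0.03, mean 0.00786) had adjusted p values from 0.743 to 0.969. In the Dlk1-Dio3 imprinted cluster 50 of 74 miRNAs had higher mean log2 values, with a list median of 0.06 (adjusted p = 0.102, and adjusted p = 0.658 with an estimated correlation). That list's adjusted p was 0.0107 without wild-type replicate 1 and 0.0220 without knockout replicate 1, but 0.550 without wild-type replicate 3 and 0.572 without knockout replicate 5, with medians down to 0.03. In the Sfmbt2 imprinted cluster 13 of 17 had a higher mean log2 value, with a list median of 0.02 (adjusted p = 0.747), but 3 of the 17 repeat the values of another member, such as miR-467a-5p and miR-467b-5p. Apart from the Hox list, 0 members of any list passed when adjusted over the list alone or over all miRNAs.

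**Figure D3:**
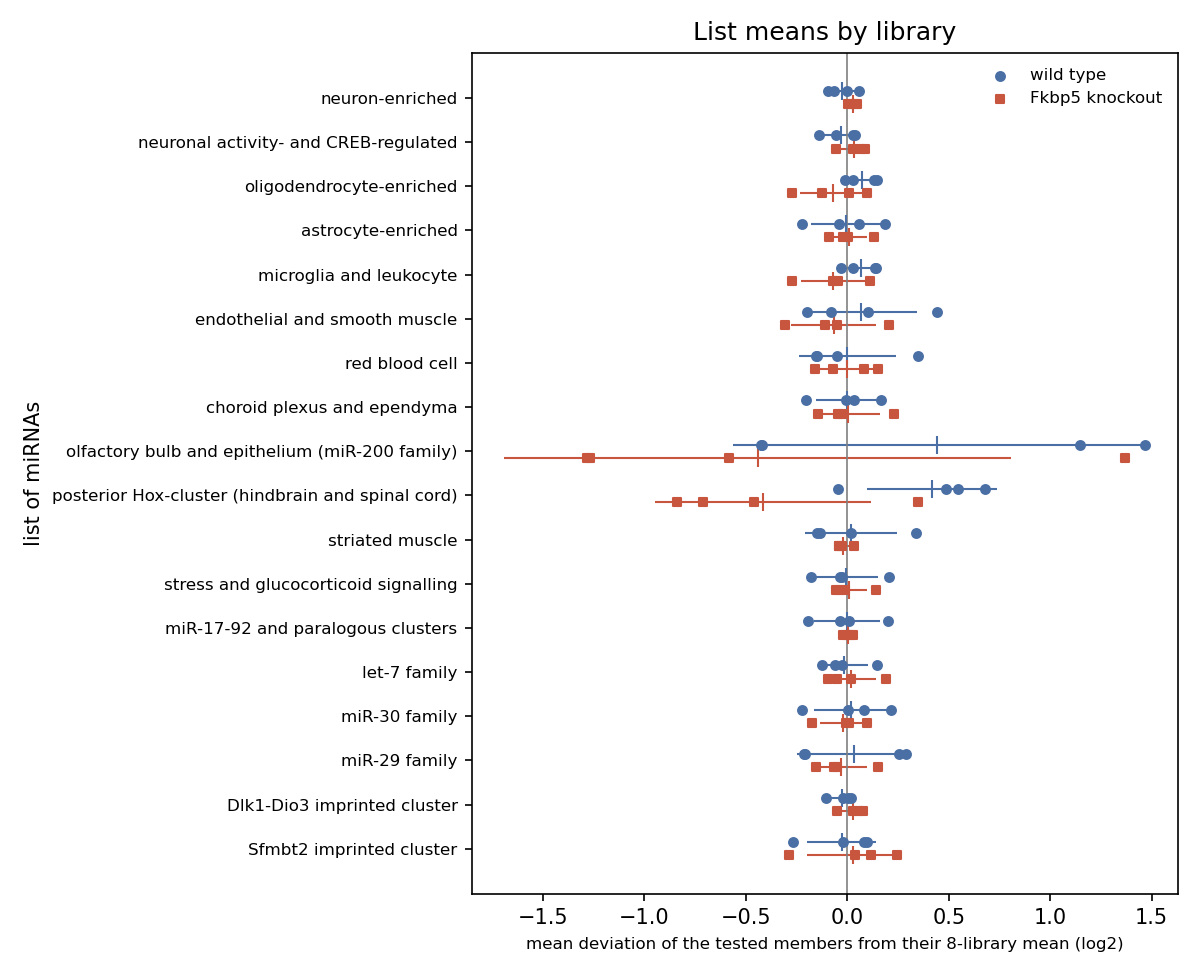
Mean deviation of each list's tested members from their mean over 8 libraries (horizontal axis, log2), by library, with group means (ticks) and 1 SD (bars). The miR-200 family spreads most, from -1.28 in knockout replicate 1 to 1.47 in wild-type replicate 2.

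Which arm of a hairpin is kept was compared through the ratio of 5p to 3p products. The ratios of miR-299a (log2 change 0.51 ± 0.19), miR-299b (0.52 ± 0.19) and miR-433 (-0.42 ± 0.17) had the smallest p values. The values of miR-299a and miR-299b nearly coincide, so they are not separate results. By limma 0 of 141 hairpins passed 0.05, and the smallest adjusted p was 0.973. These 3 were those with an unadjusted p under 0.05, a smaller share than chance gives.

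The makeup of the libraries was alike. The 5 most abundant miRNAs in each held 62.3 ± 2.19% of all values in wild type and 62.2 ± 1.83% in the knockout (SD, n = 4 each; exact permutation p = 0.914). Adjusted over 7 library measures, each p was 0.943.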

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

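The tests on blood vessel and smooth muscle miRNAs, on fragments of other RNAs and on the miR-200 family were chosen after the results they bear on had been seen. Of 178 groups of 4 libraries examined, 14 held a library far from the other 3, where chance gives 8.9. The 14 include repeats, since miR-199a-3p and miR-199b-3p share their values and those of miR-101a-3p and miR-101c nearly coincide. The 178 groups are therefore not independent. Rescaled values are given.

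Knockout replicate 2 stood apart for miR-199a-3p and miR-199b-3p (5540.2 each, the others 3682.3 to 3907.7), miR-433-3p (7015.3, the others 5716.5 to 5785.3) and miR-541-5p (33050, the others 40654 to 41076). Knockout replicate 5 stood apart for miR-338-5p (8123.9), miR-29b-3p (5973.7) and miR-146a-5p (2556.4). Wild-type replicate 1 did so for miR-451a of red blood cells (296.94, the others 487.37 to 527.49), muscle-enriched miR-206-3p (253.33, the others 84.732 to 95.51) and miR-434-3p (200220). Wild-type replicate 3 was low for miR-101a-3p (12518) and miR-101c (12562), and wild-type replicate 4 for miR-26a-5p (1592000) and miR-30a-5p (84413).

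Chance is not excluded for the unadjusted count or the list count. Of 35 splits of the 8 libraries, 22 gave at least the real 25 with an unadjusted p under 0.05 (highest other 50), and 29 gave at least the real 1 list (highest other 4). For miRNAs past the threshold the real count is 0, so all 35 splits give as many by construction and the comparison tests nothing (highest other 2).

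miR-690 was higher in all 4 knockout libraries. Removing a trend on hairpin GC left its log2 fold change at 1.201 ± 0.278, which argues against a GC trend shared by the miRNAs. Fold change and GC were barely related across miRNAs (Spearman rho 0.074), so this step could move miR-690 only slightly. The values as deposited gave 1.192 ± 0.258, so rescaling did not make the difference. The scaling factors were alike on average in both genotypes, so little else could come out. Fragments of other RNAs remain open: 5 hairpin names that take up such fragments had a median change of 0.4181 with an SE of 0.52, too wide to separate from miR-690. Genotype also remains open, and since miR-690 did not pass correction, chance does too.

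The mean of miR-143-3p, miR-199a-3p, miR-10a-5p, miR-10b-5p, miR-152-3p and miR-322-3p (median log2 fold change -0.42) was below every wild-type library in knockout replicates 1, 4 and 5 and within the wild-type range in replicate 2, although miR-322-3p and miR-10a-5p alone were below every wild-type library there too. miR-126a-3p of endothelium, at -0.07296 ± 0.112, lay above the median of -0.42 by more than 2 SE. By that arm alone, a loss of endothelium as large as that median is argued against, but a smaller loss is not excluded. Its other arm, miR-126a-5p, at -0.12 ± 0.16, lay within 2 SE of the median and cannot decide. The rule also gives no error to the median, which comes from miRNAs picked for being low, so the argument is weak. The median was -0.4266 in the values as deposited, so rescaling did not make the difference, and factors alike on average in both genotypes hardly could. Less smooth muscle or meninges may still contribute, since miR-145a-5p at -0.07938 ± 0.218 is too imprecise to decide. The other arm of its hairpin, miR-145a-3p, was lower at -0.24 ± 0.12 (not past correction). In the other direction, miR-143-5p, at a low level, was at 0.14 ± 0.34. These 6 were picked, after their values had been seen, from the 13 lower miRNAs with small p values. Their median therefore overstates the difference, and no p is given for it. Of those left out, knockout replicate 2 was below every wild-type library for miR-542-3p, miR-224-5p, miR-219a-5p and miR-490-3p. It was not for miR-101a-3p and miR-101c. The place of replicate 2 thus depends on the pick. The other arm of miR-322-3p, miR-322-5p, was at 0.08 ± 0.22. Genotype was not separated from dissection.

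The miR-200 family and miR-183 cluster were lower on average in the knockout. Within genotypes the members rose and fell together, with a median pairwise correlation of 0.9008, which is consistent with a varying amount of tissue from the edge of the dissection, such as olfactory tissue. A genotype effect cannot be told apart from this: the exact permutation p of the list mean was 0.2571, and the 95% interval of its log2 difference, -2.85 to 1.08, does not exclude a 2-fold change. miR-429-3p, named after its values were seen, differed 27.1-fold and miR-200b-3p 13.1-fold between the highest and lowest library.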

How the results depend on the processing

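The values as deposited, pseudocounts of 0.5 and 5, no mean-variance trend and counting identical miRNAs once were chosen after seeing the data. Of 432 alternative values for the 20 miRNAs named by p, 0 changed direction and 1 passed the threshold: miR-690 under a replicate block. The count past the threshold was 0 in all alternatives but the block, and 25 without adjustment; the smallest adjusted p outside the block was 0.0928. miR-690 ranged from 1.0 to 1.39, with adjusted p from 0.00252 to 0.996 (0.143 at the lowest without the block).

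The labels do not say whether the replicate numbers pair the libraries. Same-numbered libraries had correlations of 0.0652, -0.0385 and 0.132, and none correlated best with its own number. So few correlations gave no sign of pairing but cannot exclude it. A replicate block on numbers 1, 2 and 4 gave 4 miRNAs (miR-690, miR-183-5p, miR-200c-3p and miR-200b-3p), 1 hairpin arm ratio (miR-154) and 45 unadjusted, against 40 unadjusted in the same 6 libraries unblocked.

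The unadjusted count of 25 became 51 without a filter and 14 at 10 per 1000000, from the number tested, and 9 in the values as deposited, where the cause was not tested. Leaving out 1 library gave 18 to 40 (40 without wild-type replicate 3), with 0 past the threshold each time. The 1 list became 0 with an estimated correlation, 0 by fry, 0 at 10 per 1000000 (3 members left) and 0 to 3 with 1 library left out: 0 without wild-type replicate 2 or 3, and 3 without wild-type replicate 1 or knockout replicate 1. Without knockout replicate 2 the 1 list was endothelium and smooth muscle. Without 1 library the difference in the top 5 share ran from -1.10 to 0.769 percentage points, in miRNAs above 0 from -9.33 to 13.3 and in totals from -1.43 to 0.362 (units of 1000000). Other scalings moved the median of all miRNAs by at most 0.056 from its value under the main scaling. The count models and thinning were not run, because the values are labelled normalized. With 12 of 599 simulated miRNAs changed, 60.8% were recovered at 2-fold, so smaller changes in few miRNAs can be missed.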

Other observations

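The test on miR-219a was chosen after its level had been seen. Of 15 tested miRNAs with 1 locus on chromosome 17, 12 lie within 20 Mb of Fkbp5, and 0 of the 15 had an unadjusted p under 0.05 by limma, a set too small for that count to show that they do not differ. The largest difference was in miR-877-3p, 7.475 Mb away, at 0.63 ± 0.34 (not past correction). The nearest, miR-3083-3p and miR-3083-5p, 1.45 Mb away, were at -0.30 ± 0.28 and -0.18 ± 0.27. The let-7e, miR-99b and miR-125a cluster, 10.6 Mb away, was close to equal, with let-7e-5p at 0.000233 ± 0.13, miR-99b-5p at 0.14 ± 0.10 and miR-125a-5p at 0.14 ± 0.09.

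miR-219a-5p, an oligodendrocyte miRNA made from hairpins on chromosomes 2 and 17, was lower in all 4 knockout libraries (27.1 ± 4.02 against 41.7 ± 6.46, not past correction). One hypothesis was that the hairpin 5.54 Mb from Fkbp5 makes less product, which might follow from flanking DNA carried with the knockout. Its other arm, miR-219a-1-3p, was at 0.00447 ± 0.29, and lay above miR-219a-5p by 0.6084 ± 0.284 (SE). That is just over 2 standard errors, with an exact permutation p of 0.0857, so it argues only weakly against the hypothesis. The other arm of the chromosome 2 hairpin, miR-219a-2-3p, was at -0.15 ± 0.15. These values are too imprecise to show which hairpin the lower miR-219a-5p reflects.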
